A study of Homo sapiens with 12 samples.

How the data were processed

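RNA from 12 cultures of normal human lung fibroblasts in 4 groups of 3 (DMSO 0.10%, THZ1 50 nM, TGFb 10 ng/mL, TGFb with THZ1) was extracted with the Qiagen RNeasy kit and made into Illumina TruSeq Stranded Total RNA libraries, per the labels' protocols. The authors deposited raw whole-number counts per Ensembl gene, assigned on GRCh38 per the submitters' processing notes. The aligner, the counting tool, its strand setting, the annotation release and the treatment time are not given in the sources used here. The deposited count table of the series held 58302 genes and equalled the 12 single tables in every cell (0 differed). Every column could be mapped to a culture, no line lacked a gene, and 0.01% of counts lay on identifiers outside GENCODE 29, from which gene names, types and coordinates were taken. Ribosomal RNA was nearly absent, and RN7SK, RMRP and RPPH1 were listed at 0 in all libraries.

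Totals were 21.3, 26.9 and 25.1 M counts for DMSO, 19.1, 18.9 and 17.4 for THZ1, 30.4, 37.7 and 31.2 for TGFb, and 19.3, 22.5 and 18.1 for TGFb with THZ1. The libraries detected 23687 to 24981 genes. Within groups, log2 CPM correlated at r = 0.994 to 0.995 (DMSO), 0.977 to 0.988 (THZ1), 0.994 (TGFb) and 0.988 (both). No 2 libraries of the same group were duplicates by a chi-square test of their counts (2.61 per degree of freedom or more). Replicate numbers follow the order of the sample records and pair nothing.

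Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 17249 genes, TMM factors scaled the libraries, and 1 robust quasi-likelihood fit of all 12 gave 5 pairwise comparisons and the interaction of TGFb and THZ1. The biological coefficient of variation was 9.7%, with 8 residual and 8.8 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. Log2 CPM values, used for components, correlations and list tests, have a prior count of 2, while fold changes are those of the edgeR fit at its default prior count. Against simulated counts at these depths and this spread, with 200 genes changed, the test recovered 58.2% of 1.5-fold, 70.1% of 2-fold and 87.9% of 4-fold changes for TGFb against DMSO at 6.5% false calls, and for the interaction 23.9%, 55.2% and 77.3% at 4.6%. CPM values are TMM-scaled. Where a group had 0 counts, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts a ratio has its exact 95% counting interval.

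The gene lists, the main tests, the alternatives and the rule for naming genes were fixed before the data were examined. The contrast and the tests named in the closing sections as chosen after a result was seen were not. The rule named the 8 largest rises and falls for TGFb against DMSO, THZ1 against DMSO, TGFb with THZ1 against TGFb and the interaction, among called genes with mean log2 CPM of 1 or more and a standard symbol, with no overlap between the groups except for the interaction. It also named a panel of 16 genes and up to 4 members of each list described. The 30 lists (717 entries, 624 measured) covered collagens, collagen processing, matrix glycoproteins, contractile genes, TGFb targets, matrix proteases, CDK7 and the transcription machinery, immediate early genes, E2F and proliferation, p53 targets, DNA repair and replication-dependent histones. They also covered interferon-stimulated genes, inflammatory cytokines, fibroblast transcription factors, amino acid synthesis with ATF4 targets, glycolysis, sterol synthesis, endoplasmic reticulum chaperones, heat shock, apoptosis, mitochondrially encoded mRNAs, RNA polymerase III products, ribosomal proteins, lipofibroblast genes, and markers of epithelial, endothelial, immune, smooth muscle and mesothelial cells. Lists with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. When simulated collagens were raised 1.5-fold, camera called that list and 0 others. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely.

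Genes changed at least 2-fold by TGFb were used to compare the TGFb effect with and without THZ1 by a slope through the origin and by the interaction. Alternatives were DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, RLE scaling, library totals, scaling to mitochondrial or to ribosomal protein mRNAs, 2 other filters (at least 1 count, or 1 CPM in 3 libraries), fits of only the groups compared, mitochondrial and small non-coding RNAs left out, and each library left out in turn. Figures and tables were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A few single genes stayed in the fits and list tests but are not reported here.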

Results

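Primary lung fibroblasts of human origin were treated with the cytokine TGFb, which turns fibroblasts into contractile, matrix-secreting myofibroblasts, and with THZ1, a covalent inhibitor of CDK7. CDK7 is the kinase of the transcription factor TFIIH and acts on RNA polymerase II at promoters. Total RNA was sequenced from 12 cultures in 4 groups of 3: vehicle (0.10% DMSO), 50 nM THZ1, 10 ng/mL TGFb, and TGFb with THZ1. The treatment time is not given in the sources used here. The libraries held 17.4 to 37.7 M counted reads, and 17249 genes entered 1 edgeR quasi-likelihood fit of all 12. The edgeR p-values measure the spread between triplicate cultures, for which no donors are named. Camera compares the genes of a list with the other genes, and the Fisher exact and permutation tests take genes as units.

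Principal component 1 held 60.7% of the variance and separated the cultures with THZ1 from those without, and component 2 held 24.7%. THZ1 replicate 1 lay apart from the other THZ1 libraries at 61.1 on component 1, against 102.1 and 91.2. The libraries with both agents spread from 45.3 to 66.8, those with TGFb from -94.1 to -89.1 and those with DMSO from -49.6 to -49.1. Messenger RNAs of the mitochondrial genome made up 2.41 ± 0.28% of the counts with DMSO, 3.62 ± 0.40% with THZ1, 2.0 ± 0.13% with TGFb and 3.98 ± 0.11% with both (mean ± SD, n = 3). The fibronectin gene FN1 alone took 7.21 ± 0.21% of all counts with TGFb against 2.03 ± 0.14% with DMSO, and COL1A1, the gene of a type I collagen chain, took 3.71 ± 0.14% against 0.74 ± 0.04%.

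**Figure D1:**
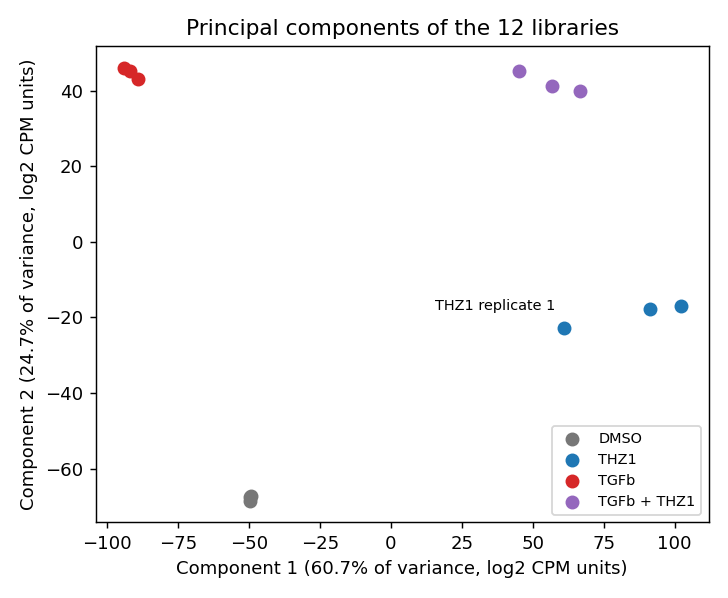
Principal components 1 and 2 of log2 CPM for the 12 libraries (n = 3 per group). Each point is a library, and THZ1 replicate 1 is marked.

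TGFb raised the myofibroblast genes by large factors. ACTA2, the smooth muscle actin of stress fibres (GRCh38, chromosome 10, 88935074 to 88991339), rose from 83.5 ± 3.56 to 2468 ± 18.5 CPM (mean ± SD, n = 3), 29.6-fold (log2 fold change 4.89 ± 0.12, adjusted p = 6.2e-15, edgeR). COL1A1 (chromosome 17, 50183289 to 50201632) rose 6.94-fold (log2 fold change 2.79 ± 0.15, adjusted p = 4.1e-11), and FN1 rose 4.9-fold (log2 fold change 2.29 ± 0.11, adjusted p = 1.9e-11). The cytokine gene IL11 rose 74.1-fold (log2 fold change 6.21 ± 0.15, adjusted p = 5.1e-15). ADH1B, an alcohol dehydrogenase gene (chromosome 4, 99304964 to 99352760), fell 259-fold, from 427 ± 10.6 to 1.62 ± 0.449 CPM (log2 fold change -8.02 ± 0.19, adjusted p = 4.4e-15).

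Among the 8 largest rises were the cartilage matrix gene COMP (8.96 ± 0.22), the gene of the joint lubricant PRG4 (8.27 ± 0.17), the elastin gene ELN (7.62 ± 0.15), the cardiac ankyrin gene ANKRD1 (7.85 ± 0.36), the homeobox gene MEOX1 (7.69 ± 0.39), and the morphogen gene GDF6 (7.29 ± 0.23) (log2 fold change ± SE, n = 3 per group throughout). The transcriptional inhibitor gene MDFI (8.90 ± 0.32) also belonged to them. KANK4, a regulator of actin and adhesion (chromosome 1, 62236979 to 62319414), had 0 counts in the DMSO libraries and 1898 with TGFb, at least 647-fold higher. The largest falls after ADH1B were those of the transporter gene SLC7A14 (-6.30 ± 0.31), the potassium channel gene KCNF1 (-5.83 ± 0.20), the sialyltransferase gene ST8SIA1 (-5.57 ± 0.25), LMOD3 (-5.30 ± 0.34), NPTX1 (-5.19 ± 0.13), FER1L6 (-5.03 ± 0.18) and the claudin gene CLDN11 (-4.93 ± 0.16). CDK7 itself (chromosome 5, 69234795 to 69277430) rose 1.66-fold with TGFb (log2 fold change 0.73 ± 0.15, adjusted p = 5.2e-04). The SMAD inhibitor gene SMAD7 (2.25 ± 0.09), the growth factor gene CCN2 (4.33 ± 0.13), TAGLN (3.33 ± 0.11), POSTN (2.66 ± 0.12), COL1A2 (1.19 ± 0.09) and COL3A1 (0.89 ± 0.17) rose as well.

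In all, 8370 genes (48.5%) changed at adjusted p < 0.05, 4195 (50.1%) of them higher, of which 1456 rose at least 2-fold, while 1667 fell as far. The split moved with the scaling: 1767 were higher and 9336 lower by library totals alone, 2047 and 4704 with mitochondrial mRNAs as the reference, and 3926 and 2790 with ribosomal protein mRNAs.

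Of 29 testable gene lists fixed beforehand, 12 were called by camera. All members of the contractile and myofibroblast list moved together: 28 of 28 measured rose, 0 fell and 0 did not pass (28 and 0 adjusted over the list alone, median 1.58, camera adjusted p = 6.01e-21). CNN1 (5.09 ± 0.14), TPM1 (4.76 ± 0.12) and ITGA11 (4.14 ± 0.10) were among its largest changes. In the endoplasmic reticulum list of chaperones and secretion genes 21 of 21 measured rose, 0 fell and 0 did not pass (21 and 0 adjusted over the list alone, median 1.13, camera adjusted p = 4.24e-12). HYOU1 (1.94 ± 0.08) and HSPA5 (1.87 ± 0.08) were examples. In the list of serine, glycine and proline synthesis and ATF4 targets 22 of 25 measured rose, 2 fell and 1 did not pass (22 and 2 adjusted over the list alone, median 1.48, camera adjusted p = 3.06e-11). CHAC1 (3.97 ± 0.13), PSAT1 (3.23 ± 0.13), SLC7A5 (3.22 ± 0.10) and MTHFD2 (3.10 ± 0.10) stood out. In the list of TGFb feedback genes and direct targets 22 of 30 measured rose, 5 fell and 3 did not pass (22 and 5 adjusted over the list alone, median 1.30, camera adjusted p = 1.29e-07). NOX4 (6.87 ± 0.17) and PMEPA1 (3.95 ± 0.10) were among these. Of the matrix glycoproteins and proteoglycans, to which ELN and COMP belong, 23 of 27 measured rose, 4 fell and 0 did not pass (23 and 4 adjusted over the list alone, median 2.35, camera adjusted p = 5.80e-13, adjusted p = 0.15 with an estimated correlation).

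Of the collagens, 16 of 21 measured rose, 3 fell and 2 did not pass (16 and 3 adjusted over the list alone, median 1.63, camera adjusted p = 1.29e-07, adjusted p = 0.19 with an estimated correlation). COL4A1 (4.44 ± 0.11), COL10A1 (3.86 ± 0.15) and COL5A1 (3.39 ± 0.12) were among its largest changes. Among the collagen processing and crosslinking enzymes 16 of 20 measured rose, 2 fell and 2 did not pass (17 and 2 adjusted over the list alone, median 1.08, camera adjusted p = 4.97e-07, adjusted p = 0.4 with an estimated correlation). The hydroxylase gene PLOD2 (2.83 ± 0.08) and the oxidase gene LOXL2 (1.80 ± 0.10) were examples. For smooth muscle and pericyte markers 7 of 10 measured rose, 2 fell and 1 did not pass (7 and 2 adjusted over the list alone, median 1.14, camera adjusted p = 0.00492, adjusted p = 0.19 with an estimated correlation). MYH11 (3.70 ± 0.12) was the highest. In the list of CDK7 and the transcription machinery 13 of 27 measured rose, 2 fell and 12 did not pass (13 and 2 adjusted over the list alone, median 0.25, camera adjusted p = 0.0233, adjusted p = 0.48 with an estimated correlation), and its median turned to -0.22 by library totals. The TFIIH helicase gene ERCC2 (1.53 ± 0.09) was the highest. A further 3 lists went down as sets. Interferon-stimulated genes included IFIT1 (-2.53 ± 0.30) and OAS3 (-1.95 ± 0.27), and 12 of 21 measured fell, 0 rose and 9 did not pass (12 and 0 adjusted over the list alone, median -0.99, camera adjusted p = 0.00495, adjusted p = 0.48 with an estimated correlation). Lipofibroblast and adventitial genes included FGF10 (-3.49 ± 0.22), CD36 (-3.44 ± 0.19) and the adipogenic receptor gene PPARG (-2.90 ± 0.13), and 11 of 19 measured fell, 4 rose and 4 did not pass (12 and 4 adjusted over the list alone, median -0.82, camera adjusted p = 0.0222, adjusted p = 0.12 with an estimated correlation). Of the inflammatory cytokines and NF-kB targets 11 of 22 measured fell, 4 rose and 7 did not pass (11 and 4 adjusted over the list alone, median -0.75, camera adjusted p = 0.0415, adjusted p = 0.39 with an estimated correlation). Here VCAM1 (-2.01 ± 0.18) and SOD2 (-1.84 ± 0.08) fell while IL6 (4.28 ± 0.15) and LIF (1.87 ± 0.08) rose. The call ended without DMSO replicate 1 (adjusted p = 0.057) or TGFb replicate 2 (0.056).

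**Figure D2:**
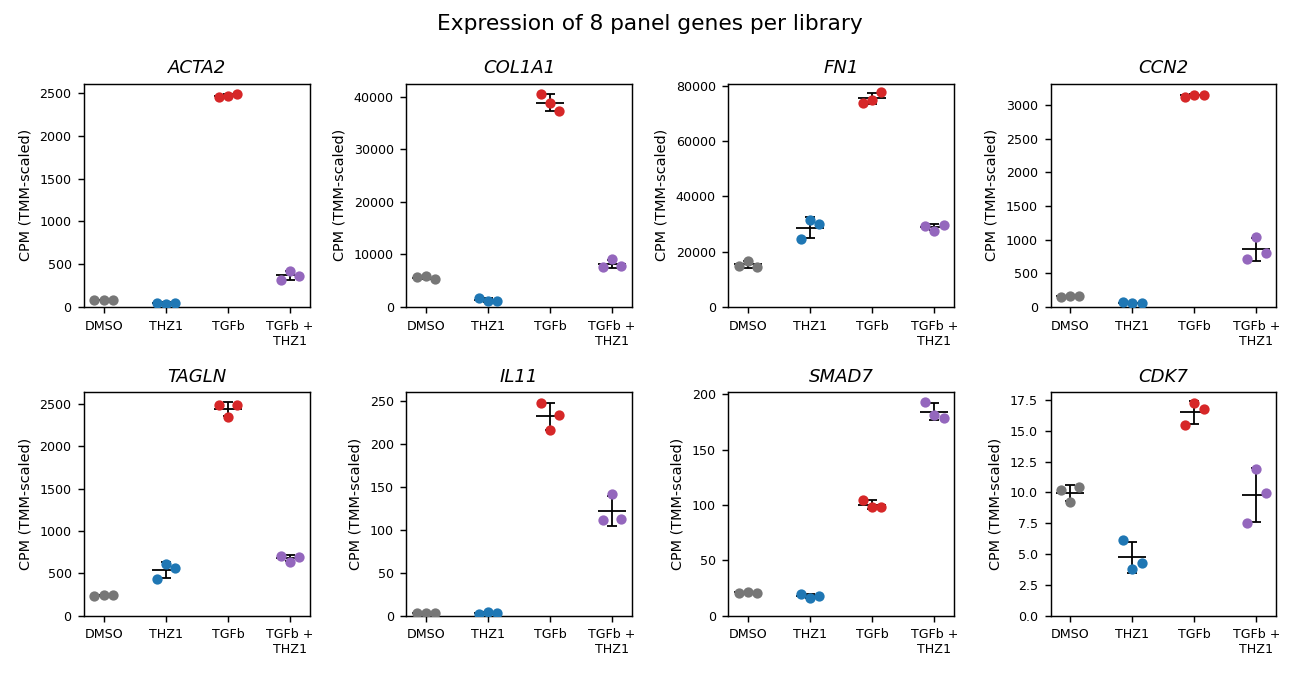
Levels of 8 genes in each library, as TMM-scaled CPM. Points are libraries, bars give the mean and lines the SD (n = 3 per group). FN1 and TAGLN with THZ1 lie below DMSO on the mitochondrial scale.

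THZ1 was compared with DMSO to see what the inhibitor did without TGFb. No other inhibitor was used, so effects through CDK7 cannot be told apart from other effects of the compound. Of the fibrillar collagen genes, COL1A1 fell from 5603 ± 290 to 1388 ± 347 CPM, 4.04-fold (log2 fold change -2.01 ± 0.14, adjusted p = 3.2e-09), and COL3A1 fell 4.4-fold (log2 fold change -2.14 ± 0.18, adjusted p = 1.9e-08), whereas COL1A2 did not pass (log2 fold change -0.03 ± 0.09, adjusted p = 0.76). CCN2 (log2 fold change -1.22 ± 0.12, adjusted p = 1.5e-07), ACTA2 (log2 fold change -0.83 ± 0.11, adjusted p = 4.0e-06) and CDK7 (log2 fold change -1.06 ± 0.17, adjusted p = 3.9e-05) fell too. FOS, the immediate early transcription factor gene (chromosome 14, 75278774 to 75282230), rose from 3.69 ± 0.705 to 98.7 ± 11.5 CPM, 26.7-fold (log2 fold change 4.74 ± 0.14, adjusted p = 1.1e-12). FN1 rose 1.87-fold (log2 fold change 0.90 ± 0.11, adjusted p = 1.5e-06), and POSTN (1.01 ± 0.11) and TAGLN (1.15 ± 0.11) rose, but all 3 values were negative with mitochondrial mRNAs as the reference. IL11 did not pass (log2 fold change 0.17 ± 0.19, adjusted p = 0.43).

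Several of the largest rises were non-coding RNAs that start beside other genes. STAG1-DT (chromosome 3, 136752630 to 136755780) had 0 counts with DMSO and was at least 307-fold higher with THZ1. BMP2K-DT (chromosome 4, 78773654 to 78775973) had 1 count with DMSO and 206 with THZ1, a ratio of 409 (95% counting interval 72.5 to 16200). ADAMTSL4-AS1 had 3 and 471 counts (ratio 311, 106 to 1520), though as an antisense gene it may hold reads of the other strand, since the strand setting of the counting is not stated. TMEM95 had 1 and 349 counts (ratio 692, 123 to 27400), and BICDL2 was at least 102-fold higher from 0 counts. Counts on the vault RNA gene VTRNA1-2, made by RNA polymerase III (chromosome 5, 140718925 to 140719013), rose 195-fold from 5 (log2 fold change 7.61 ± 0.36, adjusted p = 7.6e-11), and the transcription factor genes POU3F1 (6.96 ± 0.48) and BTBD18 (6.92 ± 0.33) rose from similarly low levels. Counts on a gene as short as VTRNA1-2 do not show which transcript they come from, and this was not tested. The largest falls were in KLHL38 (-3.82 ± 0.30), the adaptor gene CASS4 (-3.58 ± 0.18), CALHM5 (-3.12 ± 0.15), DEPP1 (-3.12 ± 0.15), PGBD5 (-3.11 ± 0.23), PRICKLE1 (-3.07 ± 0.30), LMOD3 (-2.98 ± 0.29) and SLITRK6 (-2.94 ± 0.25).

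Across biotypes, 1114 of 2147 long non-coding genes rose and 246 fell (median 0.82), as did 795 of 1834 pseudogenes with 257 lower (median 0.45) and 45 of 77 genes of other types with 6 lower (median 1.1). By contrast 4197 of 13191 protein-coding genes rose and 5726 fell (median -0.17). In total 12386 genes (71.8%) changed, 6151 higher and 6235 lower. The split depended on the scale: 3588 were higher and 9670 lower by library totals, 1445 and 12073 against mitochondrial mRNAs, and 1096 and 13368 against ribosomal protein mRNAs.

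Camera called 11 lists for THZ1, and none held with an estimated correlation. Of ribosomal protein mRNAs 60 of 62 measured rose, 0 fell and 2 did not pass (60 and 0 adjusted over the list alone, median 1.40, camera adjusted p = 1.66e-16, adjusted p = 0.47 with an estimated correlation), with a median of 0.21 on the mitochondrial scale. RPSA (2.22 ± 0.15) and RPLP1 (1.91 ± 0.13) were examples, though such genes may share reads with pseudogenes. Among mitochondrially encoded mRNAs 13 of 13 measured rose, 0 fell and 0 did not pass (13 and 0 adjusted over the list alone, median 1.11, camera adjusted p = 7.33e-05, adjusted p = 0.47 with an estimated correlation), with a median of 0.51 by library totals and -0.32 on the ribosomal protein scale. MT-CO1 (1.41 ± 0.13) and MT-ND3 (1.35 ± 0.11) were among these. Replication-dependent histone genes, whose mRNAs normally lack poly(A) tails, had a positive median under every scaling: 13 of 15 measured rose, 0 fell and 2 did not pass (13 and 0 adjusted over the list alone, median 1.92, camera adjusted p = 7.63e-05, adjusted p = 0.096 with an estimated correlation). H2BC4 (3.01 ± 0.22), H2BC8 (2.35 ± 0.20) and H4C8 (2.04 ± 0.13) were examples, and similar copies may share reads. In the DNA repair list 18 of 21 measured fell, 0 rose and 3 did not pass (18 and 0 adjusted over the list alone, median -0.79, camera adjusted p = 4.09e-04, adjusted p = 0.47 with an estimated correlation). BRCA1 (-1.59 ± 0.18) and BRCA2 (-1.36 ± 0.26) were examples. Fibroblast transcription factors were lowered broadly: 24 of 33 measured fell, 2 rose and 7 did not pass (24 and 2 adjusted over the list alone, median -0.66, camera adjusted p = 4.98e-04, adjusted p = 0.47 with an estimated correlation). TCF21 (-2.52 ± 0.15), GLI2 (-1.86 ± 0.14) and SOX4 (-1.74 ± 0.16) stood out. In sterol synthesis 16 of 21 measured fell, 5 rose and 0 did not pass (16 and 5 adjusted over the list alone, median -0.64, camera adjusted p = 0.00313, adjusted p = 0.47 with an estimated correlation). INSIG1 (-2.67 ± 0.13), MVK (-2.42 ± 0.19) and SQLE (-2.07 ± 0.21) were among these.

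The matrix lists moved up relative to the median gene even as COL1A1 and COL3A1 fell. For collagen processing enzymes 18 of 20 measured rose, 2 fell and 0 did not pass (18 and 2 adjusted over the list alone, median 1.48, camera adjusted p = 2.80e-05, adjusted p = 0.47 with an estimated correlation). P4HB (1.96 ± 0.13), PLOD1 (1.95 ± 0.12) and PCOLCE (1.89 ± 0.13) were among its largest changes. Of the collagens 16 of 21 measured rose, 3 fell and 2 did not pass (16 and 3 adjusted over the list alone, median 0.90, camera adjusted p = 0.00357, adjusted p = 0.47 with an estimated correlation), and the median was -0.27 on the mitochondrial and -0.52 on the ribosomal protein scale. COL10A1 (2.12 ± 0.18) and COL8A2 (1.98 ± 0.17) were examples. For matrix glycoproteins 20 of 27 measured rose, 5 fell and 2 did not pass (20 and 5 adjusted over the list alone, median 0.92, camera adjusted p = 0.00137, adjusted p = 0.47 with an estimated correlation), and here the median was -0.27 and -0.51 on those scales. The small proteoglycan genes DCN (1.82 ± 0.13) and LUM (1.6 ± 0.11) rose and THBS1 (-1.76 ± 0.10) fell. Matrix proteases and their inhibitors followed: 18 of 22 measured rose, 2 fell and 2 did not pass (18 and 2 adjusted over the list alone, median 0.85, camera adjusted p = 4.98e-04, adjusted p = 0.47 with an estimated correlation), again with a negative median on both those scales. PLAU (2.16 ± 0.11), MMP3 (1.94 ± 0.10) and CTSB (1.85 ± 0.11) rose and ADAMTS1 (-1.78 ± 0.08) fell. In the immediate early list 17 of 29 measured rose, 7 fell and 5 did not pass (17 and 8 adjusted over the list alone, median 0.55, camera adjusted p = 0.0173, adjusted p = 0.47 with an estimated correlation), with a median of -0.02 by library totals, -0.59 on the mitochondrial and -0.83 on the ribosomal protein scale. FOS, FOSB (3.49 ± 0.15) and IER3 (3.12 ± 0.11) stood out. The contractile list was not called (median 0.48, camera adjusted p = 0.227) and its median was -0.11 by library totals and -0.69 on the mitochondrial scale, nor were the direct TGFb targets (median 0.0, camera adjusted p = 0.823), in which the feedback gene LDLRAD4 (-2.35 ± 0.36) and SNAI2 (-2.03 ± 0.15) fell and JUNB (2.68 ± 0.13) rose.

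TGFb with THZ1 was set against TGFb alone to ask which parts of the fibrotic state THZ1 lowered. ACTA2 fell from 2468 ± 18.5 to 368 ± 51.9 CPM, 6.7-fold (log2 fold change -2.74 ± 0.11, adjusted p = 4.6e-12). COL1A1 fell 4.75-fold (log2 fold change -2.25 ± 0.14, adjusted p = 6.5e-10), CCN2 3.67-fold (log2 fold change -1.88 ± 0.12, adjusted p = 7.4e-10) and FN1 2.62-fold (log2 fold change -1.39 ± 0.11, adjusted p = 9.7e-09). TAGLN (-1.84 ± 0.11), COL3A1 (-1.44 ± 0.18), POSTN (-1.26 ± 0.11), IL11 (-0.92 ± 0.12) and COL1A2 (-0.68 ± 0.09) fell as well, and so did CDK7 (-0.75 ± 0.15). SMAD7, the feedback inhibitor of TGFb signalling, rose further, from 100 ± 3.9 to 184 ± 7.71 CPM (log2 fold change 0.88 ± 0.08, adjusted p = 5.2e-08), and MYC rose 2.09-fold (log2 fold change 1.07 ± 0.09, adjusted p = 9.8e-09), though both turned negative on the mitochondrial scale.

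The 8 largest falls included ANKRD1 (-5.19 ± 0.30), a target of mechanical and YAP signalling, and stress genes driven by ATF4: INHBE (-5.0 ± 0.21), ADM2 (-4.65 ± 0.22), TRIB3 (-4.15 ± 0.16) and CHAC1 (-3.98 ± 0.14). CHAC1, a glutathione-degrading enzyme gene, went from 94.7 ± 2.81 CPM with TGFb to 6 ± 1.38 with both, close to its 6.02 ± 0.789 with DMSO. The receptor gene CMKLR2 (-3.76 ± 0.18), AKNA (-3.51 ± 0.12) and the antisense gene L3MBTL2-AS1 (-3.55 ± 0.21) were the others, the last uncertain for want of a stated strand setting. Largest rises again fell on genes near 0 without THZ1: TMEM95 had 0 counts with TGFb and was at least 648-fold higher, STAG1-DT had 1 and 334 counts (ratio 590, 105 to 23400), and BMP2K-DT 1 and 246 (ratio 434, 77.3 to 17200). Also among them were VTRNA1-2 (7.76 ± 0.37), BTBD18 (7.38 ± 0.35), BICDL2 (6.75 ± 0.21), NUP210L (6.40 ± 0.45) and the beta-Klotho gene KLB (6.37 ± 0.35). FOS rose 62.4-fold (log2 fold change 5.96 ± 0.15, adjusted p = 7.7e-14).

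Together 12206 genes (70.8%) changed, 6130 higher and 6076 lower. On the mitochondrial scale the split was 1889 and 11718, and on the ribosomal protein scale 1749 and 12500.

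Camera called 13 lists here, and 2 of them held with an estimated correlation, ATF4 targets and histones. In the list of amino acid synthesis and ATF4 targets 22 of 25 measured fell, 1 rose and 2 did not pass (22 and 1 adjusted over the list alone, median -1.64, camera adjusted p = 9.32e-08). DDIT3 (-3.04 ± 0.16) and MTHFD2 (-2.64 ± 0.09) beside TRIB3 and CHAC1 were among these. Of the contractile genes 22 of 28 measured fell, 3 rose and 3 did not pass (22 and 3 adjusted over the list alone, median -1.19, camera adjusted p = 3.20e-07, adjusted p = 0.17 with an estimated correlation). ACTG2 (-3.46 ± 0.10), LDB3 (-2.99 ± 0.19) and SYNPO2 (-2.46 ± 0.11) were among its largest changes. Among matrix glycoproteins 18 of 27 measured fell, 4 rose and 5 did not pass (18 and 4 adjusted over the list alone, median -0.92, camera adjusted p = 0.0011, adjusted p = 0.47 with an estimated correlation). ASPN (-3.21 ± 0.17), ELN (-3.06 ± 0.12) and THBS1 (-2.57 ± 0.10) fell and FBLN1 (2.17 ± 0.12) rose. For collagens 14 of 21 measured fell, 5 rose and 2 did not pass (14 and 5 adjusted over the list alone, median -0.91, camera adjusted p = 0.0108, adjusted p = 0.47 with an estimated correlation). COL5A1 (-1.89 ± 0.11) fell, whereas COL14A1 (1.90 ± 0.12) and COL18A1 (1.54 ± 0.14) rose. In the endoplasmic reticulum list 14 of 21 measured fell, 5 rose and 2 did not pass (14 and 5 adjusted over the list alone, median -0.31, camera adjusted p = 0.0326, adjusted p = 0.17 with an estimated correlation). HERPUD1 (-2.23 ± 0.14), CREB3L1 (-2.23 ± 0.15) and XBP1 (-2.15 ± 0.10) were examples. DNA repair and sterol synthesis were lowered as with THZ1 alone. In the repair list 14 of 21 measured fell, 1 rose and 6 did not pass (14 and 1 adjusted over the list alone, median -0.75, camera adjusted p = 0.00214, adjusted p = 0.46 with an estimated correlation). BRCA1 (-2.06 ± 0.18) and BRIP1 (-1.72 ± 0.24) were examples. Of the sterol genes 16 of 21 measured fell, 2 rose and 3 did not pass (16 and 2 adjusted over the list alone, median -0.72, camera adjusted p = 0.00128, adjusted p = 0.46 with an estimated correlation). MVK (-1.93 ± 0.18) and INSIG1 (-1.72 ± 0.12) stood out.

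On the rising side, all histone genes passed: 15 of 15 measured rose, 0 fell and 0 did not pass (15 and 0 adjusted over the list alone, median 2.37, camera adjusted p = 9.26e-06). H2BC4 (3.97 ± 0.23) and H2BC8 (3.85 ± 0.21) were examples. Of ribosomal protein mRNAs 60 of 62 measured rose, 0 fell and 2 did not pass (60 and 0 adjusted over the list alone, median 1.21, camera adjusted p = 3.61e-14, adjusted p = 0.46 with an estimated correlation), with a median of 0.12 on the mitochondrial scale. For mitochondrially encoded mRNAs 13 of 13 measured rose, 0 fell and 0 did not pass (13 and 0 adjusted over the list alone, median 1.02, camera adjusted p = 1.13e-04, adjusted p = 0.46 with an estimated correlation), with a median of 0.93 by library totals and -0.20 on the ribosomal protein scale. Immediate early genes rose: 22 of 29 measured rose, 5 fell and 2 did not pass (22 and 5 adjusted over the list alone, median 1.07, camera adjusted p = 3.24e-05, adjusted p = 0.11 with an estimated correlation), while the median was -0.02 on the mitochondrial and -0.15 on the ribosomal protein scale. FOSB (4.25 ± 0.13), NR4A2 (4.10 ± 0.14) and IER2 (2.51 ± 0.11) were examples. Of interferon-stimulated genes 14 of 21 measured rose, 1 fell and 6 did not pass (14 and 1 adjusted over the list alone, median 1.04, camera adjusted p = 0.00856, adjusted p = 0.47 with an estimated correlation), with medians of -0.03 and -0.17 on those scales. OAS3 (2.42 ± 0.28), IFIT1 (2.30 ± 0.31) and MX1 (1.93 ± 0.39) were examples. In glycolysis 15 of 25 measured rose, 6 fell and 4 did not pass (15 and 6 adjusted over the list alone, median 0.49, camera adjusted p = 0.0493, adjusted p = 0.46 with an estimated correlation), a call that ended in 9 of 12 leave-one-out fits (adjusted p 0.052 to 0.066) and a median that reversed on both reference scales. CA12 (3.69 ± 0.14), ALDOC (1.64 ± 0.10) and PKM (1.64 ± 0.09) were among these. Direct TGFb targets were not called (median 0.36, camera adjusted p = 0.25), with a median of -0.72 on the mitochondrial scale: 16 of 30 measured rose, 10 fell and 4 did not pass (17 and 10 adjusted over the list alone), with SMAD3 (1.93 ± 0.09), ID2 (1.79 ± 0.11) and JUNB (2.19 ± 0.13) up.

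**Figure D3:**
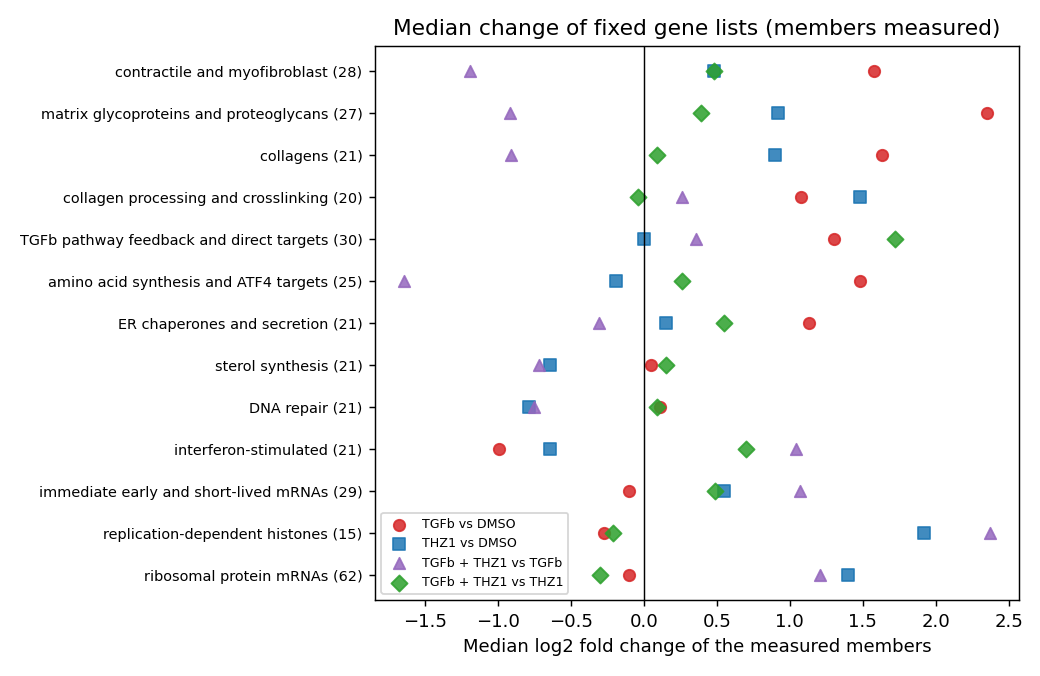
Median log2 fold change of 13 gene lists in 4 comparisons (TMM scaling). In THZ1 against DMSO and both agents against TGFb, medians above 0 turn negative on the mitochondrial or ribosomal protein scale, except for histones, for ribosomal protein mRNAs on the mitochondrial scale and, with THZ1 alone, for collagen processing. Several medians near 0 in the other comparisons change sign too.

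Genes raised at least 2-fold by TGFb were then followed as a set. Of 1456 such genes, including ACTA2, COL1A1 and FN1, 957 (65.7%) fell when THZ1 was added and 174 (12%) rose, while 32.4% of all other genes fell (Fisher exact odds ratio 4, p = 2.0e-135). The overlap expected of independent lists was 512.9, and in simulated data without a THZ1 effect on TGFb-treated cells 0% fell, or 31.7% with the THZ1 effect of untreated cells added. The simulations kept the TGFb libraries that both comparisons share, with genes drawn independently. With the THZ1 effect added, 30.94 to 33.16% of raised genes fell over the draws. This argues against independent noise in the shared libraries as the source of the excess. Deviations common to many genes were not simulated, and the Fisher test takes genes as independent. Of 1667 genes lowered by TGFb, including ADH1B, CLDN11 and FGF10, 1088 (65.3%) rose with THZ1 and 142 (8.5%) fell (Fisher exact odds ratio 3.93, p = 4.4e-149), against an independent overlap of 592.4 and, in the same simulations, 0% and 31.85%. On the mitochondrial scale 689 of 2271 such genes rose (30.3%) and 739 fell. On the ribosomal protein scale 457 of 1388 rose (32.9%) and 430 fell. Of the raised genes 90.6% and 92.1% fell on these scales. No simulation was run on them.

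The interaction term asked whether the TGFb effect itself differed under THZ1. For the raised genes the TGFb effect under THZ1 was 0.548 of that without it (slope), and for the lowered genes 0.306. With log2 CPM of the 3 libraries with both agents taken singly, the slopes had an SD of 0.032 and 0.049. The means of the other groups were held fixed there, so these SDs leave out their spread. With equal effects simulated, the slopes were 0.898 and 0.933 and edgeR called no interaction. With THZ1 effects simulated only in cells without TGFb, a real difference, the slopes were 0.811 and 0.938. The effect was then smaller for 588 raised and 500.7 lowered genes and larger for 340.5 and 382 (means of 10 draws). In the data the effect was smaller for 795 raised genes (54.6%) and larger for 33, and smaller for 1014 lowered genes (60.8%) and larger for 3. TAGLN, a calponin-family actin binder, rose 10-fold with TGFb alone but by only 0.34 ± 0.10 on the log2 scale under THZ1 (interaction log2 fold change -2.99 ± 0.15, adjusted p = 6.3e-10). FN1 rose only without THZ1: with the inhibitor present its change was 0.00 ± 0.11 and did not pass (interaction log2 fold change -2.29 ± 0.16, adjusted p = 1.2e-08). ACTA2 kept part of its response (interaction -1.91 ± 0.15). COL1A1 rose 6.94-fold without and 5.89-fold with THZ1, from a lower base, and the interaction did not pass (log2 fold change -0.24 ± 0.19, adjusted p = 0.42) and changed sign with the scaling. SMAD7 gained, with an interaction of 1.10 ± 0.12. COL3A1 (0.70 ± 0.24) was positive, a call that ended in 10 of 12 leave-one-out fits.

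**Figure D4:**
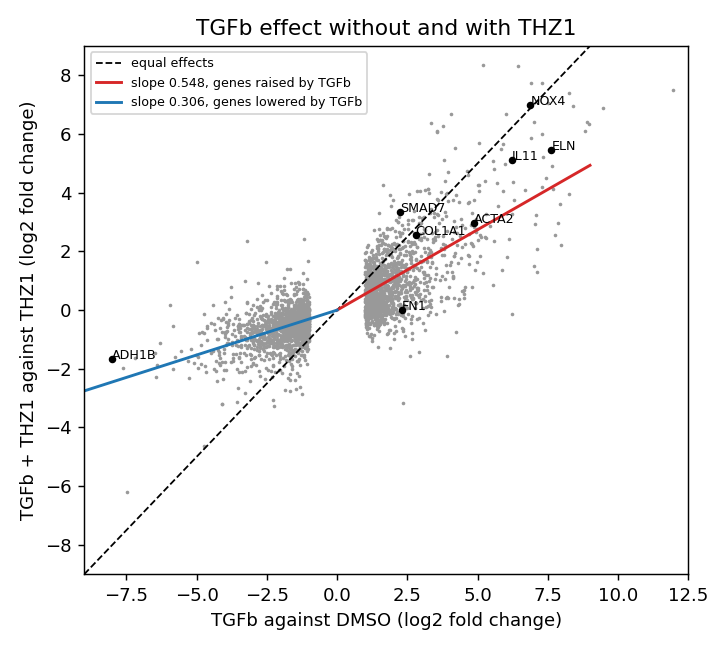
TGFb effect without THZ1 (horizontal) and with THZ1 (vertical) as log2 fold changes of genes that changed at least 2-fold with TGFb. The dashed line marks equal effects and the fitted slopes are 0.548 and 0.306 (n = 3 per group).

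Among fixed lists, 13 were called for the interaction, and the contractile, endoplasmic reticulum and ATF4 lists held with an estimated correlation. The contractile interaction was negative for 25 of 28 measured, positive for 0 and not passed for 3 (27 and 0 adjusted over the list alone, median -1.26, camera adjusted p = 3.72e-23). CNN1 (-3.26 ± 0.18), MYH11 (-3.26 ± 0.17), LDB3 (-3.01 ± 0.43) and ITGA11 (-2.99 ± 0.13) were among its largest changes. For amino acid synthesis and ATF4 targets it was negative for 18 of 25 measured, positive for 1 and not passed for 6 (19 and 2 adjusted over the list alone, median -1.17, camera adjusted p = 1.29e-12). PSAT1 (-3.42 ± 0.18), CHAC1 (-3.19 ± 0.22) and MTHFD2 (-2.42 ± 0.13) were examples. For endoplasmic reticulum genes it was negative for 13 of 21 measured, positive for 0 and not passed for 8 (14 and 0 adjusted over the list alone, median -0.69, camera adjusted p = 1.91e-08). HYOU1 (-1.71 ± 0.11), HSP90B1 (-1.50 ± 0.12) and HSPA5 (-1.34 ± 0.11) stood out. For matrix glycoproteins the term was negative for 22 of 27 measured, positive for 1 and not passed for 4 (22 and 1 adjusted over the list alone, median -1.39, camera adjusted p = 6.91e-16, adjusted p = 0.17 with an estimated correlation). ASPN (-3.81 ± 0.29), SPARC (-2.65 ± 0.15) and BGN (-2.35 ± 0.15) were among these. For collagens the term was negative for 14 of 21 measured, positive for 2 and not passed for 5 (14 and 2 adjusted over the list alone, median -0.92, camera adjusted p = 3.11e-09, adjusted p = 0.17 with an estimated correlation). COL10A1 (-3.44 ± 0.22), COL11A1 (-3.08 ± 0.17) and COL5A1 (-2.60 ± 0.16) led them. For collagen processing enzymes the term was negative for 16 of 20 measured, positive for 1 and not passed for 3 (16 and 1 adjusted over the list alone, median -1.16, camera adjusted p = 6.25e-11, adjusted p = 0.24 with an estimated correlation), such as LOXL3 (-2.03 ± 0.21) and LOXL4 (-1.74 ± 0.15). For smooth muscle markers the term was negative for 6 of 10 measured, positive for 2 and not passed for 2 (6 and 2 adjusted over the list alone, median -1.06, camera adjusted p = 0.00418, adjusted p = 0.18 with an estimated correlation).

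For interferon-stimulated genes the term was positive for 14 of 21 measured, negative for 0 and not passed for 7 (16 and 0 adjusted over the list alone, median 1.52, camera adjusted p = 5.91e-07, adjusted p = 0.23 with an estimated correlation). IFIT1 (4.17 ± 0.44), MX1 (3.17 ± 0.56) and OAS3 (2.54 ± 0.38) were examples. For immediate early genes the term was positive for 16 of 29 measured, negative for 6 and not passed for 7 (17 and 7 adjusted over the list alone, median 0.56, camera adjusted p = 0.00132, adjusted p = 0.17 with an estimated correlation). NR4A2 (3.04 ± 0.17), EGR3 (1.71 ± 0.18) and ZFP36 (1.56 ± 0.14) were positive and CCN1 (-1.69 ± 0.12) negative. For fibroblast transcription factors the term was positive for 15 of 33 measured, negative for 4 and not passed for 14 (16 and 4 adjusted over the list alone, median 0.39, camera adjusted p = 0.00588, adjusted p = 0.58 with an estimated correlation). SOX4 (2.58 ± 0.22) and FOXF2 (1.51 ± 0.14) stood against MEOX1 (-3.54 ± 1.04) and GLI1 (-2.80 ± 0.39). For direct TGFb targets it was positive for 12 of 30 measured, negative for 6 and not passed for 12 (16 and 8 adjusted over the list alone, median 0.34, camera adjusted p = 0.0498, adjusted p = 0.17 with an estimated correlation), a call that ended in 8 of 12 leave-one-out fits (adjusted p 0.05 to 0.079). LDLRAD4 (2.54 ± 0.38), SMAD6 (2.35 ± 0.21) and SMAD3 (1.62 ± 0.12) were among these. For matrix proteases the term was negative for 9 of 22 measured, positive for 5 and not passed for 8 (10 and 5 adjusted over the list alone), with a median of 0.23 by library totals (median -0.27, camera adjusted p = 0.028, adjusted p = 0.58 with an estimated correlation). ADAM12 (-2.22 ± 0.13) and MMP3 (-2.17 ± 0.13) were negative and PLAT (1.92 ± 0.15) positive. For ribosomal protein mRNAs the term was negative for 0 of 62 measured, positive for 0 and not passed for 62 (0 and 0 adjusted over the list alone), with a median of 0.30 by library totals (median -0.21, camera adjusted p = 0.00752, adjusted p = 0.83 with an estimated correlation). Proteases did not pass without THZ1 replicate 2 or without replicate 2 of the group with both agents (adjusted p 0.088 and 0.09), nor did ribosomal protein mRNAs without either of these or THZ1 replicate 3 (0.053 to 0.24).

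The interaction passed for 4136 genes (24%), 2178 positive and 1958 negative, with 7308 and 729 by library totals and 1865 and 897 on the ribosomal protein scale. The count was 8037 by library totals, 2031 on the mitochondrial scale, 1265 against a 1.5-fold change and 7010 without THZ1 replicate 1, and the slope of the lowered genes was 0.184 on the ribosomal protein scale.

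TGFb was also tested on cells held in THZ1. IL11 rose 34.7-fold (log2 fold change 5.12 ± 0.16, adjusted p = 3.0e-13), CCN2 12.8-fold (log2 fold change 3.67 ± 0.13, adjusted p = 2.5e-12), SMAD7 10.2-fold (log2 fold change 3.35 ± 0.09, adjusted p = 8.9e-14) and ACTA2 7.85-fold (log2 fold change 2.97 ± 0.12, adjusted p = 5.3e-12). In the list of direct TGFb targets 23 of 30 measured rose, 5 fell and 2 did not pass (23 and 5 adjusted over the list alone, median 1.72, camera adjusted p = 6.77e-13). NOX4 (7.0 ± 0.22), LDLRAD4 (6.11 ± 0.24) and PMEPA1 (4.69 ± 0.11) were among its largest changes. In the endoplasmic reticulum list 14 of 21 measured rose, 0 fell and 7 did not pass (14 and 2 adjusted over the list alone, median 0.55, camera adjusted p = 1.93e-04), and these were the 2 lists that held with an estimated correlation. CREB3L2 (1.37 ± 0.08) and XBP1 (1.19 ± 0.10) were examples. Of the contractile genes 19 of 28 measured rose, 0 fell and 9 did not pass (19 and 2 adjusted over the list alone, median 0.48, camera adjusted p = 1.03e-07, adjusted p = 0.12 with an estimated correlation). TPM1 (2.90 ± 0.11), SYNPO2 (2.26 ± 0.12) and CNN1 (1.83 ± 0.13) stood out. Immediate early genes included EGR2 (3.32 ± 0.14), KLF10 (3.01 ± 0.09) and GADD45B (2.38 ± 0.11), and 18 of 29 measured rose, 3 fell and 8 did not pass (19 and 4 adjusted over the list alone, median 0.49, camera adjusted p = 1.81e-05, adjusted p = 0.088 with an estimated correlation). For matrix glycoproteins 15 of 27 measured rose, 1 fell and 11 did not pass (15 and 4 adjusted over the list alone, median 0.39, camera adjusted p = 1.04e-04, adjusted p = 0.58 with an estimated correlation). COMP (6.35 ± 0.23), ELN (5.47 ± 0.14) and THBS1 (1.53 ± 0.10) were among these.

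Of interferon-stimulated genes 11 of 21 measured rose, 2 fell and 8 did not pass (11 and 2 adjusted over the list alone, median 0.70, camera adjusted p = 0.00441, adjusted p = 0.61 with an estimated correlation). In the list of CDK7 and the transcription machinery 11 of 27 measured rose, 1 fell and 15 did not pass (11 and 1 adjusted over the list alone, median 0.20, camera adjusted p = 0.00441, adjusted p = 0.58 with an estimated correlation). For collagens 10 of 21 measured rose, 2 fell and 9 did not pass (10 and 4 adjusted over the list alone, median 0.09, camera adjusted p = 0.02, adjusted p = 0.7 with an estimated correlation), and the median was -0.02 on the mitochondrial scale. COL1A1 (2.56) and COL4A1 (2.14 ± 0.10) were its largest changes. ATF4 targets followed: 12 of 25 measured rose, 1 fell and 12 did not pass (12 and 3 adjusted over the list alone, median 0.26, camera adjusted p = 0.0279, adjusted p = 0.12 with an estimated correlation). SLC7A5 (2.10 ± 0.10) was an example. Without THZ1 replicate 1 neither list passed (adjusted p = 0.19 and 0.11), nor did collagens without replicate 1 of the group with both agents (0.068). Ribosomal protein mRNAs were lower: 35 of 62 measured fell, 0 rose and 27 did not pass (46 and 0 adjusted over the list alone, median -0.30, camera adjusted p = 4.74e-06, adjusted p = 0.73 with an estimated correlation), with a median of -0.41 on the mitochondrial scale. With THZ1 present TGFb changed 5981 genes (34.7%), 3210 higher and 2771 lower, or 1154 and 2530 on the mitochondrial scale and 4047 and 434 on that of ribosomal proteins. The count was 8754 without THZ1 replicate 1, 3986 without THZ1 replicate 3, 3802 without replicate 2 of the group with both agents, 3684 on the mitochondrial scale, 3040 from these 6 libraries alone and 1040 against a 1.5-fold change.

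Cells given both agents were finally compared with DMSO, to see how far they remained from the untreated state. ACTA2 stayed 4.41-fold higher (log2 fold change 2.14 ± 0.11, adjusted p = 5.9e-11), SMAD7 8.73-fold (log2 fold change 3.13 ± 0.09, adjusted p = 3.5e-14) and IL11 39.1-fold (log2 fold change 5.29 ± 0.15, adjusted p = 4.3e-14). COL1A1 ended 1.46-fold higher (log2 fold change 0.55 ± 0.14, adjusted p = 0.0021), a difference that vanished to -0.01 by library totals and reversed on the mitochondrial scale, and COL3A1 ended lower (log2 fold change -0.55 ± 0.17, adjusted p = 0.0095). CDK7 did not pass (log2 fold change -0.02). Only the direct TGFb targets held with an estimated correlation among 14 called lists: 23 of 30 measured rose, 5 fell and 2 did not pass (24 and 5 adjusted over the list alone, median 2.0, camera adjusted p = 2.42e-06). Of matrix glycoproteins 24 of 27 measured rose, 2 fell and 1 did not pass (24 and 2 adjusted over the list alone, median 1.28, camera adjusted p = 1.32e-07, adjusted p = 0.36 with an estimated correlation), with a negative median on the mitochondrial scale. Of contractile genes 23 of 28 measured rose, 1 fell and 4 did not pass (23 and 1 adjusted over the list alone, median 1.03, camera adjusted p = 3.19e-06, adjusted p = 0.19 with an estimated correlation), with a negative median on the mitochondrial scale. For collagens 18 of 21 measured rose, 2 fell and 1 did not pass (18 and 2 adjusted over the list alone, median 1.14, camera adjusted p = 6.05e-05, adjusted p = 0.36 with an estimated correlation), with a negative median on the mitochondrial scale. Of their processing enzymes 18 of 20 measured rose, 1 fell and 1 did not pass (18 and 1 adjusted over the list alone, median 1.26, camera adjusted p = 1.52e-05, adjusted p = 0.39 with an estimated correlation), with a median of -0.04 on the mitochondrial scale.

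Of ribosomal protein mRNAs 60 of 62 measured rose, 0 fell and 2 did not pass (60 and 0 adjusted over the list alone, median 1.10, camera adjusted p = 1.03e-12, adjusted p = 0.39 with an estimated correlation), with a negative median on the mitochondrial scale. For mitochondrially encoded mRNAs 13 of 13 measured rose, 0 fell and 0 did not pass (13 and 0 adjusted over the list alone, median 1.25, camera adjusted p = 3.24e-05, adjusted p = 0.39 with an estimated correlation), with a median of 0.69 by library totals and 0.15 on the ribosomal protein scale. Of immediate early genes 19 of 29 measured rose, 6 fell and 4 did not pass (19 and 6 adjusted over the list alone, median 1.28, camera adjusted p = 1.10e-04, adjusted p = 0.12 with an estimated correlation), with a median of -0.02 on the mitochondrial scale. Of histones 13 of 15 measured rose, 0 fell and 2 did not pass (13 and 0 adjusted over the list alone, median 1.85, camera adjusted p = 1.37e-04, adjusted p = 0.072 with an estimated correlation), with a positive median under every scaling. Of the proteases 18 of 22 measured rose, 3 fell and 1 did not pass (18 and 3 adjusted over the list alone, median 1.15, camera adjusted p = 6.57e-04, adjusted p = 0.37 with an estimated correlation), with a negative median on the mitochondrial scale. For endoplasmic reticulum genes 15 of 21 measured rose, 4 fell and 2 did not pass (15 and 4 adjusted over the list alone, median 0.93, camera adjusted p = 0.00207, adjusted p = 0.074 with an estimated correlation), with a negative median on the mitochondrial scale. In glycolysis 16 of 25 measured rose, 5 fell and 4 did not pass (18 and 5 adjusted over the list alone, median 0.56, camera adjusted p = 0.025, adjusted p = 0.36 with an estimated correlation), with a negative median on the mitochondrial scale. DNA repair and sterol genes stayed down. Of the repair genes 14 of 21 measured fell, 0 rose and 7 did not pass (14 and 0 adjusted over the list alone, median -0.64, camera adjusted p = 3.28e-04, adjusted p = 0.36 with an estimated correlation). For sterols 16 of 21 measured fell, 4 rose and 1 did not pass (16 and 4 adjusted over the list alone, median -0.59, camera adjusted p = 0.00207, adjusted p = 0.36 with an estimated correlation), with MVK (-1.99 ± 0.18), INSIG1 (-1.71 ± 0.12) and ACAT2 (-1.55 ± 0.10). The edgeR test called 11809 genes (68.5%), 6344 higher and 5465 lower, with 3529 and 9220 by library totals, 1164 and 12883 on the mitochondrial and 1648 and 12102 on the ribosomal protein scale.

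The THZ1 effects with and without TGFb, which share no library, were related across all genes (Pearson r = 0.81, Spearman rho = 0.77). In both, 9400 genes such as FOS, BRCA1, COL1A1 and VTRNA1-2 changed in the same direction and 618 in opposite directions, against 4382 expected of independent lists. The TGFb effects with and without THZ1 were related less closely (r = 0.64, rho = 0.55), with 3699 genes such as IL11, NOX4 and ELN in the same and 252 in opposite directions, against 1451. The median log2 fold change of all genes was -0.61 for THZ1 by library totals, -1.18 on the mitochondrial and -1.43 on the ribosomal protein scale, and -0.11, -1.10 and -1.23 for THZ1 added to TGFb. For TGFb alone these medians were -0.48, -0.22 and 0.11, so every direction given for THZ1 is relative to the median gene.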

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

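The contrast of matrix and contractile genes with direct targets in this part was chosen after the list results were seen, and its 2 tests were written down before their own values were. The design asks for 1 difference between groups, that of the TGFb effect with and without THZ1, and the results here are those for which the interaction term passed, 4136 genes in all. Among 40 splits of the 12 libraries, the real one and others drawn at random from all possible, the next highest count was 4, and 1 split, the real one, gave as many. For the 1809 TGFb-responsive genes with a smaller response under THZ1, 1 split was as large and the next gave 0. The other splits put the TGFb and THZ1 effects inside the groups, which widens the spread and leaves few calls with or without an interaction. They therefore cannot exclude chance for either count of genes. Nor is chance excluded for the 13 called lists, since 5 of the 40 splits gave as many and the highest of the others gave 16.

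The interaction was most negative for the growth factor binding protein gene IGFBP3 (-5.05), which stood at 1431 ± 81 CPM with TGFb and 132 ± 18.5 with both agents, followed by the membrane repair gene DYSF (-4.50), PRG4 (-4.31), SLFNL1 (-4.22), the keratin gene KRT7 (-4.13), the retinol dehydrogenase gene HSD17B6 (-4.04) and the sortilin receptor gene SORCS2 (-3.97). KANK4 (-4.46) had 0 counts with DMSO, so that its value depends on the prior count, and its call ended in 10 of the leave-one-out fits. The interaction was most positive for ADH1B (6.35), SLC7A14 (5.16), ST8SIA1 (4.19), the interferon-induced IFIT1 (4.17), CLDN11 (4.14), RASL11A (4.08), the muscle kelch gene KLHL41 (4.01) and the collagen gene COL21A1 (3.97). ADH1B fell with TGFb and stood at 51.5 ± 8.52 CPM with both. The interaction also takes in the change with THZ1 alone, so the levels given here for IGFBP3 and ADH1B do not by themselves give its size.

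Of the panel, TAGLN (-2.99), FN1 (-2.29), POSTN (-2.27), ACTA2 (-1.91), IL11 (-1.09), CCN2 (-0.65) and COL1A2 (-0.65) were negative. MYC (0.51), SMAD7 (1.10) and COL3A1 (0.70) were positive, the last with a call that ended in 10 of 12 leave-one-out fits. The lists called were contractile genes (adjusted p = 3.7e-23), matrix glycoproteins (6.9e-16), amino acid synthesis and ATF4 targets (1.3e-12), collagen processing (6.3e-11), collagens (3.1e-09), endoplasmic reticulum genes (1.9e-08), interferon-stimulated genes (5.9e-07), immediate early genes (1.3e-03), smooth muscle markers (4.2e-03), fibroblast transcription factors (5.9e-03), ribosomal protein mRNAs (7.5e-03), matrix proteases (2.8e-02) and direct TGFb targets (5.0e-02). With an estimated correlation 10 of these 13 calls were lost, all but the contractile, ATF4 and endoplasmic reticulum lists. Of the 4 matrix and contractile lists in the contrast below 3 were lost (camera adjusted p = 0.17, 0.17 and 0.24), and so was that of the direct targets (0.17). Leaving out single libraries ended the calls of direct targets (8 of 12 fits), proteases (2) and ribosomal protein mRNAs (3).

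The mean interaction of 96 matrix and contractile genes was -1.29 (77 negative, 4 positive and 15 not passed), and that of 30 direct targets 0.32 (6, 12 and 12), a difference of -1.61. TGFb alone raised both sets by similar means (1.85 and 1.54), but under THZ1 by 0.56 and 1.86. On the TMM scale THZ1 without TGFb moved them by 0.64 and -0.01, so that part of the contrast comes from higher values of the first set in cells without TGFb. Regression on the TGFb effect and the expression level left -1.44 (SD of 10000 random lists 0.12, permutation p 1e-04, the smallest they can give). The sets were picked for the pattern, and random lists lack the correlation between genes of a list. The permutation p therefore cannot decide whether those are the cause. In these genes most of the difference remained after a linear fit of both. Without THZ1 replicate 1 the difference was -1.74, which argues against that library as the source. No biological explanation was tested, and RNA turnover over the unstated treatment time stays open.

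For each pairwise comparison the 6 libraries allow 10 splits, too few for a share under 0.05. The other splits also mix the treatments within groups, which widens the spread, so low counts of genes from them do not exclude chance. The counts of genes by edgeR were 8370 for TGFb (highest other 0), 12386 for THZ1 (0), 12206 for THZ1 added to TGFb (0), 11809 for both against DMSO (0) and 957 for genes raised by TGFb that fell with THZ1 (0), each with 1 split as large. For TGFb under THZ1 the count was 5981 (1 split), and the highest other, 2637, came from the split that put THZ1 replicate 1 with replicates 2 and 3 of both agents. Lists called were 12 for TGFb (highest other 12, 2 splits as large), 11 for THZ1 (12, 3 splits), 13 for THZ1 added to TGFb (12, 1 split), 10 for TGFb under THZ1 (13, 3 splits) and 14 for both against DMSO (14, 3 splits).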

How the results depend on the processing

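Every alternative below was chosen before the data were examined. No paired analysis was possible because the groups share no replicate numbers in the labels. DESeq2 called 8396, 12276, 12186, 6574, 11815 and 4468 genes for TGFb, THZ1, THZ1 added to TGFb, TGFb under THZ1, both against DMSO and the interaction, against 8370, 12386, 12206, 5981, 11809 and 4136 by edgeR, with 0 opposite signs. Of 457 values of named genes, DESeq2 gained 2 calls and lost or reversed none. Over all leave-one-out fits 0 calls reversed, 70 of 5484 lost their call and 7 gained one.

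Testing against a 1.5-fold change left 3454, 7095, 6706, 1040, 6518 and 1265 genes, in that order, as a stricter hypothesis must. TGFb under THZ1 gave 3684 genes on the mitochondrial scale and 3040 when only its 6 libraries were fitted, and from 3802 (without replicate 2 of both agents) to 8754 (without THZ1 replicate 1) when single libraries were left out. The interaction gave 8037 genes by library totals, 2031 on the mitochondrial scale, and from 3340 (without DMSO replicate 2) to 7010 (without THZ1 replicate 1). For these the cause was not tested. The other 4 comparisons stayed within 1.5 times of their counts in every leave-one-out fit, and at least 61.9% of the calls of each comparison were shared, with 0 of opposite sign. Every alternative not given here left each count of genes within 1.5 times. Directions were less stable than counts. For THZ1, 7680 genes had the same sign by TMM and on the mitochondrial scale and 1739 the opposite sign, with a call in both, and on the ribosomal protein scale 7331 and 2761. For THZ1 added to TGFb these were 7965 and 1457, then 7825 and 2067, and for both against DMSO 6629 and 2539, then 7113 and 2023. By library totals they were 5942 and 92 for TGFb, 9823 and 380 for THZ1, and 8994 and 317 for both.

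The slope of genes raised by TGFb, 0.548, was 0.645 by library totals, 0.608 on the ribosomal protein scale and 0.498 with all genes of at least 1 count. That of the lowered genes, 0.306, was 0.240 and 0.184 on the first 2 of these. The share of TGFb-lowered genes that rose with THZ1, 65.3%, was 30.3% on the mitochondrial and 32.9% on the ribosomal protein scale, since these scales moved the median of all genes in that comparison to -1.10 and -1.23. For the slopes the cause was not tested.

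With an estimated correlation camera called 4 lists for TGFb, 0 for THZ1, 2 for THZ1 added to TGFb, 2 for TGFb under THZ1, 1 for both against DMSO and 3 for the interaction, and fry called 19, 21, 22, 16 and 24 for the pairwise comparisons. By library totals camera lost 4, 0, 0, 0, 1 and 2 of its calls, in the same order, and gained 1, 1, 0, 0, 2 and 1. On the mitochondrial scale it lost 3, 2, 1, 1, 2 and 1 and gained 1, 1, 2, 1, 1 and 0. The ribosomal protein list of the interaction also reversed by library totals and was no longer called (camera adjusted p = 6.0e-01). That scale moved the median interaction of all genes to 0.53 and that of the list to 0.30, and the cause of the changed camera result was not tested.

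Scales that shift every gene reversed small changes by construction. By library totals, TGFb against DMSO gave CDK13 -0.17, CCNH -0.01, MCL1 -0.45 and CDK12 -0.22, THZ1 against DMSO gave IL11 -0.42, MYC -0.02, MCL1 -0.46 and CDK12 -0.47, and both against DMSO gave CDK13 -0.44, COL1A1 -0.01, MCL1 -0.24, COL1A2 -0.06 and CDK12 -0.40. On the mitochondrial scale THZ1 against DMSO gave IL11 -1.01, FN1 -0.29, POSTN -0.17, MYC -0.59, MCL1 -1.03, TAGLN -0.04 and CDK12 -1.03. THZ1 added to TGFb gave SMAD7 -0.21, MYC -0.02 and MCL1 -0.79, and both against DMSO gave CDK13 -1.17, COL1A1 -0.76, FN1 -0.40, MCL1 -0.97, COL1A2 -0.80 and CDK12 -1.13. No other value of these genes with a call in either fit reversed under these 2 scales, while 8 lost and 5 gained a call by library totals and 43 lost and 4 gained one on the mitochondrial scale. At these depths the self-test recovered 23.9% of 1.5-fold interactions. It changed far fewer genes than the interaction called in the data, which makes the adjusted p-value threshold stricter there. This share therefore does not show how often small differences of the TGFb effect were missed in the data.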

Other observations

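Tests chosen after the result was seen in this part are those of base composition and of background reads for non-coding RNAs, of a weaker response of THZ1 replicate 1, and of gene length. The remaining fixed lists were not called by camera in any comparison. Cell cycle genes of the E2F list moved both ways with THZ1: 16 of 30 measured fell, 8 rose and 6 did not pass (16 and 8 adjusted over the list alone), with AURKA (-2.51 ± 0.20), TOP2A (-2.12 ± 0.25) and MCM6 (-2.01 ± 0.12) down and FOXM1 (2.89 ± 0.14) up (median -0.55, camera adjusted p = 0.252). With TGFb, 14 of 30 measured fell, 3 rose and 13 did not pass (15 and 3 adjusted over the list alone), with AURKA (-1.76 ± 0.16) down and CCNA2 (2.01 ± 0.14) up (median -0.37, camera adjusted p = 0.0565). Of the p53 targets 12 of 23 measured fell, 5 rose and 6 did not pass (15 and 6 adjusted over the list alone) with TGFb, among them PLK2 (-2.72 ± 0.15) (median -0.23, camera adjusted p = 0.0769). With THZ1 10 of 23 fell, 6 rose and 7 did not pass (median 0.01, camera adjusted p = 0.767). The stress cytokine gene GDF15 (2.52 ± 0.13) rose there while CDKN1A (-1.05 ± 0.12) fell.

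The other lists are given for THZ1 against DMSO. Of apoptosis regulators 4 of 21 rose and 6 fell (adjusted p = 0.773), and of heat shock genes 3 of 16 rose and 6 fell (0.579). Of markers of other cell types, 4 of 6 epithelial genes rose and 1 fell (0.292), 1 of 6 endothelial genes rose and 3 fell (0.642), 4 of 5 immune genes rose and 0 fell (0.0947), and 2 of 4 mesothelial genes rose and 1 fell (0.773). Medians of the epithelial and mesothelial lists turned negative on the mitochondrial scale. Of RNA polymerase III products only VTRNA1-2 was measured, so that list was not tested.

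Non-coding genes of low expression (mean log2 CPM under 2) that start within 5 kb of an expressed coding gene and point away from it rose with THZ1 relative to the median gene: of 176 such genes 114 rose and 10 fell (median 1.54, bootstrap SD 0.15), and their coding partners had a median of -0.17. Of 151 non-coding genes over 100 kb from expressed coding genes 57 rose and 21 fell, with a median of 0.28 (SD 0.12). This argues against a rise of low background reads that is equal at all positions. A smaller general rise is not excluded, since more genes rose than fell in every class. The rise was not limited to divergent genes: the medians were 0.93 for 64 such genes downstream (33 rose and 8 fell), 0.84 for 1265 that overlap coding genes (651 and 114) and 0.64 for 233 others (104 and 28). The difference of medians between divergent and distant genes, 1.26, was 1.30 without THZ1 replicate 1, which argues against that library as the source. After regression on GC content, length and expression level 0.64 (SD 0.24) remained, so these cannot be told apart from position. The strand setting of the counting stays open, and no biological explanation was tested.

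THZ1 replicate 1 differed from replicates 2 and 3 by a chi-square per degree of freedom of 38.18 and 22.4, against 3.87 between those and 6.78 to 15.55 among the libraries with both agents. With all 3 thinned to 17.4 M counts the smaller value was 5.74 times that of the other pair, which argues against depth. Its deviations ran against the THZ1 effect measured in TGFb-treated cells (Pearson r = -0.49 over 12528 genes), so a weaker response may be the cause but stays open. The values of 0.46 and 0.26 for replicates 2 and 3 are no separate comparison, since the 3 deviations cancel for each gene. Untreated RNA mixed in would need 11.4 ± 0.5% by 482 lowered genes and 21.0 ± 2.1% by 156 raised genes, a difference of -9.7 points (bootstrap SD 2.2), which leaves it open too. The design names no biological difference within a group, so none beyond the weaker response was tested.

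Whether longer genes fell more with THZ1 was also tested, and the relation was weak. The log2 fold change of 13178 coding genes had a Spearman rho with genomic span of -0.09, and of -0.04 with TGFb present, and the median was 0.18 in the shortest of 10 groups by span (median 3.6 kb) and -0.24 in the longest (269.4 kb).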
